A study of Bos taurus with 34 samples.

How the data were processed

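Genomic DNA from white blood cells of cattle was compared by array comparative genomic hybridisation, in which a test DNA and a reference DNA labelled with different dyes compete for the same probes. Per the labels, 4 µg of DNA was labelled, the test animal carried Cy5 and the reference animal, Angus-4, carried Cy3 on all 34 arrays, and no dyes were swapped. A log2 ratio above 0 therefore means more signal from the test animal than from Angus-4, and dye and probe effects do not cancel. Groups were the breeds and subspecies in the labels, with Angus and Holstein as taurine and Nellore and Brahman as indicine cattle. Animals were named by breed and number as in the labels.

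Arrays of 3 designs were used. Design 1 held 4 animals (Nellore-3, Nellore-4, Brahman-1 and Brahman-2), design 2 held 23 animals and the self-hybridisation of Angus-4, and design 3 held repeat arrays of 6 animals. Designs 1 and 2 shared all 418336 probe positions, and design 3 shared 252 of its 414700 positions with them. Arrays were scanned on 8 days, numbered here in order, and 5 of these days held the arrays of design 2. Scan day 2 held Angus and Nellore, scan day 3 all 4 Holstein, scan day 4 the Brahman, and scan days 7 and 8 another 12 Angus.

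The deposited scanner files hold processed signal intensity values for each dye, which per the file headers came from Feature Extraction 10.7.1.1, or 10.5.1.1 for the 2 arrays of Nellore-3 and Nellore-4. The submitters' processing notes name version 10.7.1.1 for all arrays. The settings of background subtraction and dye normalisation are not given in the sources used here. The deposited value table holds a log10 ratio of red over green that differed from the scanner files' own log ratio by at most 4.4e-16, so its direction is test over reference and it was not centred further. The medians of its columns over autosomal probes were between -0.00161 and 0.00932. Positions are those of the probe names in the files. The headers name the build HGSC Btau_3.1, while positions reach 161070874 on chromosome 1. No assembly of that build was used here, so the build name was not checked and positions should be read as the files' own. The gene table used here belongs to a different assembly, so no gene was named, and the gene lists and named genes fixed beforehand were not tested.

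For each probe, log2(red over green) was computed from the processed signals and centred on the autosomal median of the array, without loess or quantile normalisation. Control spots and probes with an outlier flag (between 7 and 817 per array of design 1, 2 or 3) were removed. Medians were taken over non-overlapping windows of 10 neighbouring probes with at least 3 values, which gave 40573 autosomal windows with a median span of 6873 bp (interquartile range 463 to 32823 bp). Windows stood in for genes in every comparison. Probes on the X chromosome were kept out of the tests. Red signals were well above background for 81.5 to 99.8% of probes and green signals for 75.7 to 99.96% over the 23 animals. The SD of probe log2 ratios was between 0.18 and 0.34. Precision is limited by the number of animals.

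A linear model with 1 mean per breed was fitted to the 23 animals of design 2 with limma 3.58.1 (R 4.3.3, lmFit and eBayes), and 5 contrasts were tested. Windows with a Benjamini-Hochberg adjusted p under 0.05 were called. The subspecies contrast weighted both breeds of a subspecies equally. The 4 animals of design 1 were not in the model and served as further animals. Copy number segments were found on each array by a recursive interval search over probes in genome order, with a score of at least 6, at least 5 probes, an absolute mean log2 ratio of at least 0.3 and at most 500 probes per interval searched. Numbers of segments were compared by two-sided exact permutation tests. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

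Windows were named by a rule set before the data were examined. It took the 10 largest differences each way for the subspecies contrast, and the 5 largest each way for the others, among called windows whose animals all lay on the same side of the mean of the other group. Of windows within 500 kb of one another that changed the same way, only the largest took a place, and the rest were counted with it. For segments, the 5 windows covered in most animals were named, gains and losses apart.

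The window test was run on simulated data made from the 40573 windows of the subspecies contrast, with 50 windows changed at each size. It recovered 80% of changes of 0.3, 98% of changes of 0.6 and all changes of 1 and 2, with 10 false calls. The segment search was run on the shuffled self-hybridised array with 100 segments planted at each size. It recovered 27 gains and 39 losses of 10 probes at a log2 ratio of 0.5 and -0.5, 92 gains and 98 losses of 20 probes, and all segments at 1 and -1, with 43 to 57 segments found elsewhere. Shuffling removes signal shared by neighbouring probes. In its true probe order the same array gave 275 segments, so 43 to 57 understates those found without a difference in copy number.

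Alternatives covered normexp background correction (offset 50), loess (span 0.3), the deposited value table, a filter on dim probes, outlier probes kept, means, windows of 5 and 20 probes, round of slide use, slide and slide position as blocks, animal number as a block, the self-hybridised array as an Angus, the 4 further animals, equal weights for animals, stricter thresholds and leaving out animals. Scan day as a random block, scan day 2 alone, and fits without the 12 Angus of scan days 7 and 8, without 3 noisy arrays (probe SD over 0.3) or without Brahman were added after the data were examined. So was a fit with dim signals raised, in which a signal not well above background took the lowest well-above-background signal of its array and dye, or its own if higher, before the ratios were centred again. A correction for GC content was not run, because probe sequences were not used here.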

Results

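The series compared DNA copy number between taurine cattle (Angus, a beef breed, and Holstein, a dairy breed) and indicine cattle (Nellore and Brahman, humped zebu breeds), with each animal measured against the same Angus animal. It held 34 arrays of 27 animals besides the reference. Design 2 measured 15 Angus, 4 Holstein, 2 Nellore and 2 Brahman animals and the reference against itself. Design 1 measured 2 further Nellore and 2 further Brahman at the same probe positions, and design 3 measured 6 of the animals again with other probes. Median processed signals over the 23 animals of design 2 were between 845 and 945 in red and between 844 and 938 in green. All differences below are log2 ratios to Angus-4 with standard errors from limma, and positions are those of the files, whose headers name the build HGSC Btau_3.1.

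The largest measured differences between indicine and taurine cattle lay on chromosome 5 near 63 Mb, where neighbouring stretches changed in opposite directions. From 63420204 to 63420583 the indicine mean was 3.24 ± 0.56 higher (SE; adjusted p = 0.000686), with Nellore at 4.86 ± 0.57 (SD, n = 2), Brahman at 4.36 ± 0.01 (SD, n = 2), Angus at 0.87 ± 1.07 (SD, n = 15) and Holstein at 1.89 ± 2.004 (SD, n = 4). Green signals, from the reference, were well above background for 15% of values in Brahman and 36% in Angus there, and red signals for 25.3% in Angus. With signals not well above background raised to the lowest signal that was, the difference was 1.82 ± 0.48 (SE; adjusted p = 0.0255). With fewer animals the difference stayed about as large with a wider error and was not called: 3.05 ± 0.64 within round B of slide use (adjusted p = 0.0563), 3.22 ± 0.96 within scan day 2 (0.282) and 2.85 ± 0.76 without the 12 Angus of scan days 7 and 8 (0.0815). Another 16 called windows between 62969336 and 63803446 were also higher, but over this region as a whole the repeat arrays gave 0.01 in Nellore-2, -0.07 in Nellore-3 and -0.05 in Brahman-1, against 0.59, 0.51 and 0.27 on the first arrays. That region also holds lower windows from 63674162 on. Over its part from 62969336 to 63504627 the repeat arrays gave 0.17 in Nellore-2, 0.002 in Nellore-3 and 0.14 in Brahman-1. Values on the first arrays were 0.65, 0.59 and 0.31 there, and Angus-2 and Angus-3 stood at 0.15 and -0.05 on the repeat arrays. High values at 63420204 were not limited to indicine animals, since Angus-2 stood at 4.54, Holstein-1 at 3.64 and Holstein-4 at 3.53. From 63824732 to 63825354 the indicine mean was lower by a difference of -3.64 ± 0.29 (SE; adjusted p = 1.22e-09), and another 10 called windows between 63674162 and 63978607 were lower too. All 15 Angus lay between -0.04 and 0.11 in this window and the Holstein at -0.10 ± 0.02 (SD, n = 4), while Nellore-1 stood at -5.37, Nellore-2 at -4.99, Brahman-4 at -4.12 and Brahman-3 at -0.22. Red signals were well above background there for 20% of values in Nellore and 50% in Brahman, so values far below 0 are limits, and with dim signals raised the difference was -2.48 ± 0.14. Of the further animals, Nellore-4 stood at -6.35, Brahman-2 at -5.18, Nellore-3 at -1.03 and Brahman-1 at -0.94.

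**Figure D1:**
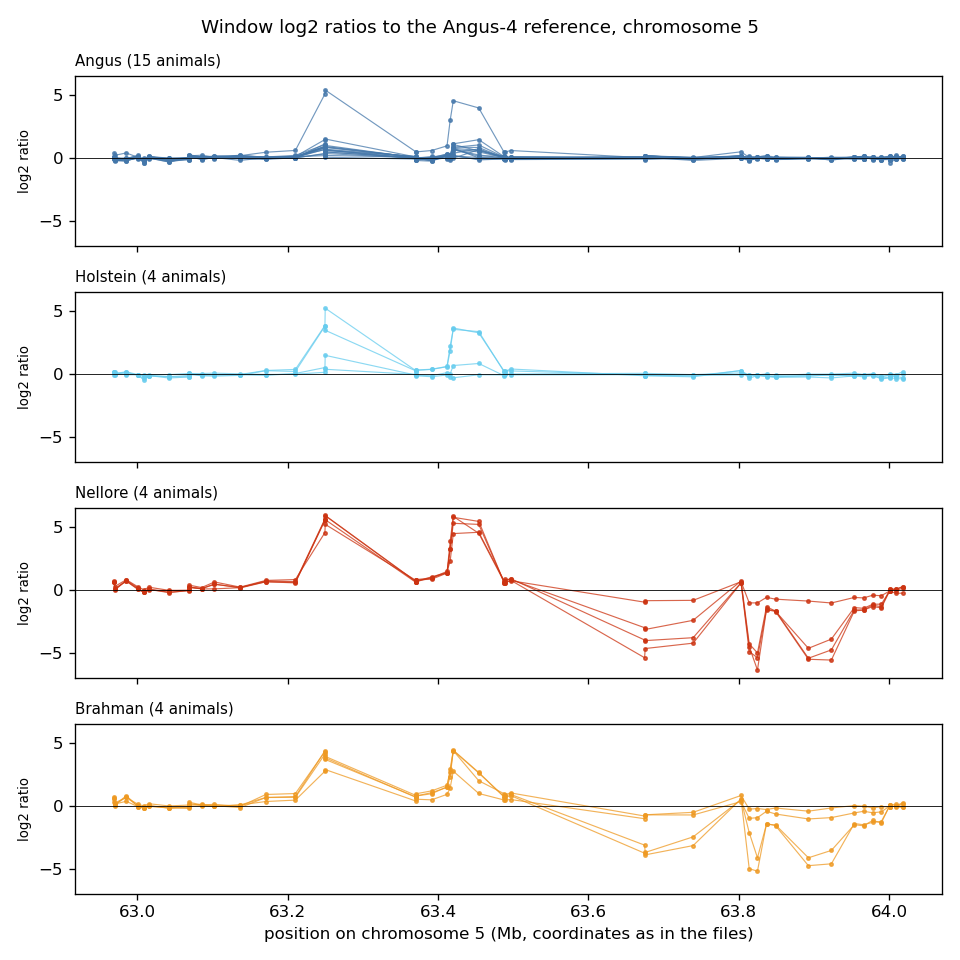
Median log2 ratio to Angus-4 (vertical axis) of each window of 10 probes by position on chromosome 5 in Mb (horizontal axis), with a panel for each breed and a line for each animal of designs 1 and 2. All 4 Nellore stood above 4 at 63420204, and the window at 63824732 was between -4.99 and -6.35 in 3 Nellore and at -1.03 in Nellore-3.

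Among the other regions higher in indicine cattle, the window on chromosome 15 from 79178823 to 79179177 differed by 0.71 ± 0.05 (SE; adjusted p = 5.05e-11), with 16 more called windows between 78794211 and 79520938. The windows on chromosome 2 from 35240671 to 35242260 and from 93461024 to 93465953 were 0.97 ± 0.09 and 0.72 ± 0.08 higher, that on chromosome 15 from 46915258 to 46915810 was 0.82 ± 0.11 higher, and that on chromosome 18 from 63454247 to 63478663 was 1.05 ± 0.19 higher. At 35240671 green signals were well above background for 35% of values in Brahman. The difference there was still called but smaller with only probes well above background on every array (0.54 ± 0.06) and with normexp (0.59 ± 0.05). Windows on chromosome 24 from 13120167 to 13121326 and on chromosome 4 from 34811257 to 35506154 were 1.25 ± 0.11 and 1.08 ± 0.12 higher, and those on chromosome 6 from 95551339 to 95551781 and on chromosome 11 from 35145542 to 35145887 were 1.25 ± 0.19 and 1.297 ± 0.21 higher. In these last 4 windows the difference came mainly from Nellore, with means between 1.90 and 2.23 against -0.01 to 0.55 in Brahman. With subspecies as the only factor the windows on chromosomes 11 and 6 differed by 0.98 ± 0.32 and 0.96 ± 0.32 (adjusted p = 0.125 and 0.127).

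Among the other regions lower in indicine cattle, the window on chromosome 29 from 7826985 to 7852642 differed by -0.66 ± 0.04 (SE; adjusted p = 1.49e-11) and that on chromosome 7 from 49061514 to 49061866 by -0.62 ± 0.05 (SE; adjusted p = 1.36e-09). The window on chromosome 15 from 44148744 to 44149229 differed by -1.79 ± 0.11, with Nellore at -3.54 ± 0.94 (SD, n = 2) and Brahman at -0.04 ± 0.04 (SD, n = 2). Windows on chromosome 8 from 65224705 to 65225089, chromosome 9 from 86948720 to 86949075 and chromosome 5 from 62272299 to 62272784 differed by -0.97 ± 0.16, -0.93 ± 0.15 and -0.78 ± 0.11. The first was -0.47 without Nellore-1 and -1.47 without Nellore-2. Windows on chromosome 13 from 54022591 to 54029215 and chromosome 16 from 26664454 to 26664788 differed by -0.58 ± 0.08 and -0.55 ± 0.07, and within scan day 2, without Brahman, by -0.21 ± 0.13 (adjusted p = 0.756) and -0.31 ± 0.06 (0.0234). The window on chromosome 14 from 13267137 to 13308175 differed by -0.63 ± 0.16, with an adjusted p of 0.0452, and by about as much, -0.61 ± 0.18, with scan day as a random block (adjusted p = 0.112).

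**Figure D2:**
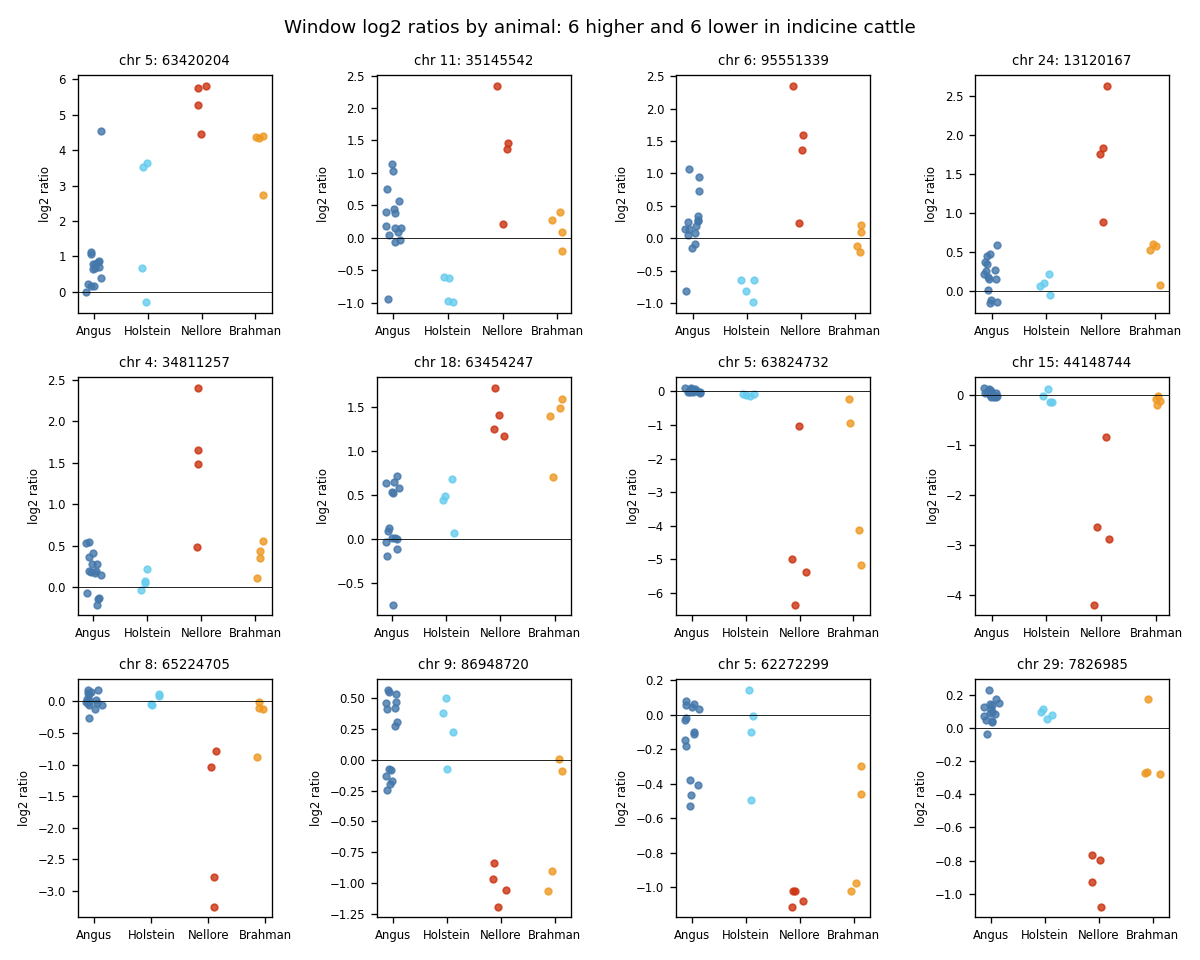
Log2 ratio to Angus-4 (vertical axes) in 12 windows, 6 higher and 6 lower in indicine cattle, by breed (horizontal axes), with a point for each of the 15 Angus, 4 Holstein, 4 Nellore and 4 Brahman. On chromosome 29 at 7826985 every Nellore lay below every Angus, whose lowest value was -0.03, while Brahman-1 stood at 0.17.

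In all, 563 of 40573 windows differed between the subspecies, 339 higher and 224 lower in indicine cattle, in 157 higher and 150 lower regions. Of these, 270 differed by at least 0.3 and 39 by at least 1. The further 4 indicine animals differed from the taurine mean in the same direction in 557 of the 563 windows (98.9%). Of windows that were not called, 68.4% did so too, while unchanged groups simulated with the same shared taurine mean gave 57.7% over all windows and 75.02% among as many windows with the largest simulated differences. These simulations hold no scan-day effect, and the further Brahman shared scan day 4 with the Brahman of the fit. Within round B, which held Brahman and no Nellore, 13 of the 20 named windows were not past the threshold, with differences 0.0201 to 0.943 times as large. Without Nellore-2 the count was 293 and without Brahman-3 it was 342. Within scan day 2, the only day of design 2 that held both subspecies, 331 windows differed between Nellore and Angus, and with scan day as a random block 390 differed between the subspecies.

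Nellore was lower than Angus in regions of chromosomes 5 and 15. The window on chromosome 5 from 63824732 to 63825354 differed by -5.21 ± 0.39 (SE; adjusted p = 1e-10), with 12 more called windows between 63674162 and 64001003. With dim signals raised it was -3.99 ± 0.19. The window on chromosome 15 from 44084760 to 44085114 differed by -4.54 ± 0.07 (SE; adjusted p = 8.89e-29), with 12 more between 43850992 and 44181154; Nellore-1 stood at -4.77, Nellore-2 at -4.40, Nellore-4 at -2.71 and Nellore-3 at -0.96, while Brahman stood at -0.04 ± 0.09 (SD, n = 2) and the Angus between -0.18 and 0.09. Red signals there were well above background for 40% of values in Nellore, and the difference was -2.77 ± 0.06 with dim signals raised and -1.57 ± 0.06 with only probes well above background on every array. The window on chromosome 23 from 26286419 to 26329930 differed by -1.996 ± 0.19 and that on chromosome 14 from 13101267 to 13266120 by -1.87 ± 0.31. On chromosome 11 from 98623308 to 98643017 the difference of -2.67 ± 0.39 rested mainly on Nellore-1, at -4.67, against -0.71 in Nellore-2. Within scan day 2 it was -2.68 ± 0.75 (adjusted p = 0.232), and with only probes well above background on every array the difference was -0.11 (adjusted p = 0.561).

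**Figure D3:**
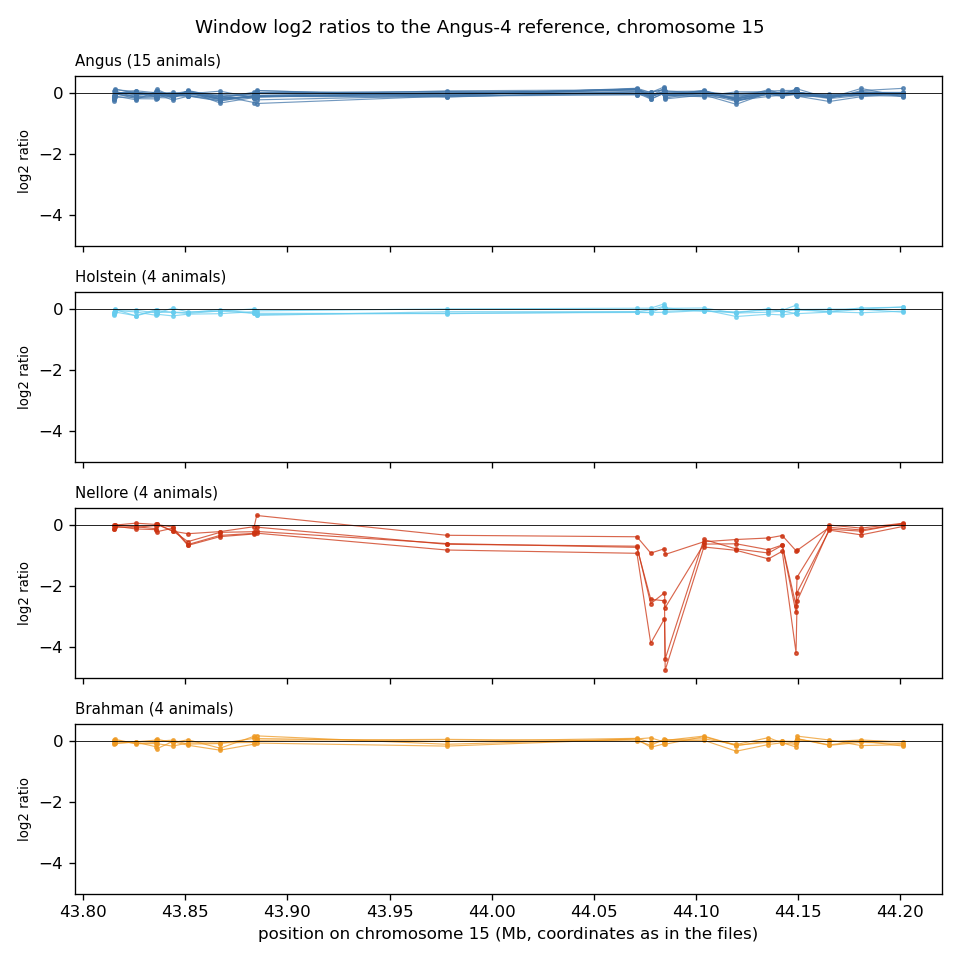
Median log2 ratio to Angus-4 (vertical axis) of each window of 10 probes by position on chromosome 15 in Mb (horizontal axis), with a panel for each breed and a line for each animal of designs 1 and 2. The window at 44084760 was between -2.71 and -4.77 in 3 Nellore and at -0.96 in Nellore-3, against -0.18 to 0.09 in Angus.

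Higher in Nellore than in Angus were the windows on chromosome 5 from 63249773 to 63250232 (4.39 ± 0.84), chromosome 24 from 13120167 to 13121326 (2.03 ± 0.15), chromosome 6 from 95555065 to 95555493 (1.88 ± 0.16), chromosome 4 from 34811257 to 35506154 (1.84 ± 0.15) and chromosome 11 from 35145854 to 35146280 (1.73 ± 0.24). The difference on chromosome 5 was 3.29 ± 1.09 within scan day 2 (adjusted p = 0.37), where Angus-2 stood at 5.39, 4.20 ± 1.17 without Nellore-1 (0.128), 4.57 ± 1.17 without Nellore-2 (0.0648) and 3.29 ± 1.21 without the 12 Angus of scan days 7 and 8 (0.502). Red signals there were well above background for 18.7% of values in Angus, and with dim signals raised the difference was 3.28 ± 0.58. In all, 480 windows differed, 269 higher and 211 lower, and 71 by at least 1. Nellore-3 and Nellore-4 differed from the Angus mean in the same direction in 479 of the 480, against 68.3% of windows that were not called. Simulated unchanged groups gave 53.8% over all windows and 63.1% among as many windows with the largest simulated differences. Without Nellore-1 the count was 297, without Nellore-2 it was 298, and in both cases the remaining Nellore was taken to vary like the other breeds. With scan day as a random block the count was 410, and within scan day 2 it was 331.

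Brahman also differed from Angus on these stretches of chromosome 5, by 3.50 ± 0.74 (SE; adjusted p = 0.0176) from 63420204 to 63420583 and by -2.31 ± 0.31 (SE; adjusted p = 6.81e-05) from 63675565 to 63675926, where Brahman-4 stood at -3.69 and Brahman-3 at -0.72. With dim signals raised these differences were 0.99 ± 0.63 (SE; adjusted p = 0.249) and -1.197 ± 0.13. The first was 3.504 ± 1.03 without Brahman-3 (adjusted p = 0.301), 3.49 ± 1.03 without Brahman-4 (0.0909) and 2.72 ± 1.097 without the 12 Angus of scan days 7 and 8 (0.23), about as large with a wider error. A window on chromosome 5 from 100505199 to 100522019 was lower by -1.41 ± 0.16, with Brahman-4 at -2.12, Brahman-3 at -0.77, the further Brahman-2 at -0.74 and the further Brahman-1 at -0.03, and with dim signals raised the difference was -0.89 ± 0.11. On chromosome 17 from 67017150 to 67017626 Brahman was 0.65 ± 0.07 higher (SE; adjusted p = 3.59e-06), at 0.71 ± 0.04 (SD, n = 2) against 0.06 ± 0.08 (SD, n = 15) in Angus, and the further Brahman-1 and Brahman-2 stood at 0.45 and 0.62. Windows on chromosome 2 from 116628052 to 116628845 and on chromosome 9 from 24834943 to 25040257 were 0.69 ± 0.13 and 0.63 ± 0.14 higher. That on chromosome 2 lay between 0.49 and 0.90 over its alternative fits, and 3 of these 25 did not pass the threshold. That on chromosome 9 rested on Brahman-4, at 0.93, against -0.07 in Brahman-3, -0.20 in Brahman-1 and -0.18 in Brahman-2, and was 0.13 ± 0.13 without Brahman-4 (adjusted p = 0.615). Windows on chromosome 13 from 54022591 to 54029215 and chromosome 16 from 26645390 to 26664463 were lower by -0.79 ± 0.10 and -0.69 ± 0.08, the second by -0.38 ± 0.08 without Brahman-4. The windows on chromosome 18 from 63454247 to 63478663 (0.96 ± 0.24) and chromosome 3 from 108959071 to 108960658 (-0.90 ± 0.20) differed by about as much, 0.94 ± 0.25 and -0.89 ± 0.21, with scan day as a random block (adjusted p = 0.0908 and 0.0527). Without the 12 Angus of scan days 7 and 8 the first was smaller, 0.50 ± 0.19 (adjusted p = 0.192). That on chromosome 18 was 0.52 ± 0.32 without Brahman-4 (adjusted p = 0.4) and 1.41 ± 0.32 without Brahman-3 (0.0552), with the further Brahman-1 and Brahman-2 at 1.39 and 1.496. On chromosome 3, where red signals were well above background for 20% of values in Brahman, the deposited value table gave -0.03 (adjusted p = 0.862), normexp turned the difference to 0.47, and with dim signals raised it was -1.66 ± 0.19 (adjusted p = 6.51e-06).

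In all, 443 windows differed between Brahman and Angus, 221 higher and 222 lower, and 13 by at least 1. Brahman-1 and Brahman-2 differed from the Angus mean in the same direction in 406 of the 443 (91.6%), against 68.9% of windows that were not called. The simulated values were 53.8% and 62.8%, with no scan-day effect simulated. Brahman-1 and Brahman-2 were scanned on scan day 4 like the Brahman of the fit, so their agreement cannot tell breed from scan day. Green signals were well above background for 63.7 to 78.4% of probes on these Brahman arrays. The count was 142 with scan day as a random block, 149 without the 12 Angus of scan days 7 and 8, and 86 without Brahman-3. No scan day of design 2 held both Brahman and Angus.

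Called windows of Nellore and of Brahman overlapped. Of windows higher than in Angus, 46 were called in both breeds and of lower windows 25. Lists of the same lengths from simulated unchanged groups against the same Angus shared 3.41 higher and 2.88 lower windows on average, and independent lists would share 1.47 and 1.15. Called windows lie in runs of neighbours: the higher windows formed 19 regions with 15 windows in the largest, and the lower windows 9 regions with 13 in the largest, both on chromosome 5. The differences of both breeds from Angus correlated across the 40573 windows, which are not independent, with r = 0.457. Unchanged groups simulated against the same Angus gave 0.117. The covariance was 0.00881 against 0.000812 simulated, and r was 0.373 when 8 Angus were set against Nellore and the other 7 against Brahman. The simulations hold no scan-day effect, and 12 of the 15 Angus were scanned on days without Nellore or Brahman, so they exclude nothing about scan day.

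The breeds of indicine cattle also differed from each other. On chromosome 15 from 44084760 to 44085114 Nellore was lower than Brahman by -4.55 ± 0.09 (SE; adjusted p = 3.6e-25), and on chromosome 23 from 26286419 to 26329930 by -2.10 ± 0.25. Windows on chromosome 5 from 63803421 to 63824765 (-3.38 ± 0.27), chromosome 11 from 98623308 to 98643017 (-2.77 ± 0.52) and chromosome 8 from 65224705 to 65225089 (-1.68 ± 0.28) were lower too. With dim signals raised the difference on chromosome 15 was -2.86 ± 0.08. The difference at 63803421 was -0.22 ± 0.15 with only probes well above background on every array (adjusted p = 0.716) and -1.57 ± 0.59 with the 4 further animals (0.18). On chromosome 11 it was -0.23 ± 0.10 with that filter (adjusted p = 0.482), and on chromosome 8 it was -0.68 without Nellore-1 and -2.67 without Nellore-2. Higher in Nellore were the windows on chromosome 6 from 95551339 (1.98 ± 0.34), chromosome 11 from 35145854 (1.79 ± 0.32), chromosome 24 from 13119799 (1.70 ± 0.20), chromosome 4 from 34811257 (1.63 ± 0.20) and chromosome 5 from 100505199 (1.47 ± 0.22). The difference at 100505199 was 0.96 ± 0.14 with dim signals raised and ranged from 0.70 to 2.14 over its alternative fits. In all, 201 windows differed, 83 higher and 118 lower in Nellore, and 43 by at least 1. With 2 animals in each breed the spread came mainly from the taurine animals, and without Nellore-1 the count was 112.

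Holstein differed from Angus by smaller amounts in most called windows. Higher in Holstein were the windows on chromosome 18 from 63852550 to 63874770 (0.52 ± 0.11), chromosome 19 from 24499796 to 24500125 (0.43 ± 0.09), chromosome 12 from 85270709 to 85286979 (0.34 ± 0.07) and chromosome 10 from 106191687 to 106206042 (0.34 ± 0.07). The last 2 rested largely on Holstein-4, at 0.71 and 0.82, and were 0.19 ± 0.06 and 0.19 ± 0.05 without it (adjusted p = 0.439 and 0.334). Lower in Holstein were those on chromosome 11 from 35145542 to 35145887 (-1.08 ± 0.21), chromosome 6 from 95551339 to 95551781 (-0.999 ± 0.19), chromosome 13 from 19279216 to 19279619 (-0.78 ± 0.15) and chromosome 15 from 46833593 to 46857914 (-0.48 ± 0.11). In all, 108 windows were called, 59 higher and 49 lower, with adjusted p between 0.02 and 0.0471 in the named windows. With scan day as a random block limma called 0 windows, although 3957 had an unadjusted p under 0.05, and each named window had an adjusted p between 0.129 and 0.213. The named differences stayed between 0.962 and 1.01 times their size under that block, and their standard errors were 1.04 to 1.16 times as large. That block cannot remove a scan-day effect from Holstein, so these sizes do not exclude one. Without the 12 Angus of scan days 7 and 8 the differences on chromosomes 11 and 6 were -0.55 ± 0.21 and -0.63 ± 0.20. Neither was called (limma, adjusted p = 0.323 and 0.261), nor was any other of the 10 named windows. All 4 Holstein were scanned on a day of their own, and the count was 2 without the 12 Angus of scan days 7 and 8, 19 without Holstein-1, 10 without Holstein-2, 213 without Holstein-3, 2 without Holstein-4 and 70 without either Nellore-1 or Nellore-2.

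Another 2 windows named for Holstein and Angus varied among the Angus. On chromosome 8 from 86052068 to 86551300 Holstein was lower by -5.27 ± 1.15 (SE; adjusted p = 0.0434). The 12 Angus of scan days 7 and 8 lay between 6.31 and 7.20 there, the 3 Angus of scan day 2 between 0.05 and 0.07, Brahman-1 at 6.08 and Brahman-3 at 6.16. On chromosome 14 from 9437303 to 9437799 Holstein was 0.69 ± 0.15 higher, and the same 12 Angus lay between -1.15 and -0.81 against -0.17 to -0.10 in the other 3. Without these 12 Angus the differences were -0.02 ± 0.81 on chromosome 8 and 0.05 ± 0.11 on chromosome 14 (limma, adjusted p = 0.996 and 0.882). Median log2 ratios of X chromosome probes were between -0.82 and -0.78 in the 12 Angus of scan days 7 and 8, -0.83 in Brahman-1, -0.79 in Brahman-3 and between -0.05 and 0.00 in all other animals of designs 1 and 2. Fits without these 12 Angus therefore change X chromosome ratio and scan day together, which the fits cannot tell apart. The Brahman, however, shared scan day 4. On chromosome 8 Brahman-2 stood at 0.52 and Brahman-4 at -0.06. On chromosome 14 Brahman-1 and Brahman-3 stood at -0.70 and -0.99, against -0.11 in Brahman-2 and -0.27 in Brahman-4. In these 2 windows the Brahman thus differed with X chromosome ratio on a shared scan day. That argues against scan day as the whole cause there, and other windows stay open.

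Indicine animals carried 599 ± 205 segments (SD, n = 4) and taurine animals 459 ± 178 (SD, n = 19), a difference of 140 that was within the spread between animals (two-sided exact permutation test, p = 0.167). Holstein carried 560 ± 340 (SD, n = 4) and Angus 432 ± 110 (SD, n = 15; exact permutation test, p = 0.193). Holstein-4 alone carried 1063, and without it the difference from Angus was -39.7 and that between the subspecies 173 (exact permutation test, p = 0.0182). Without Brahman-4 the subspecies differed by 239 (exact permutation test, p = 0.0422). The reference hybridised against itself gave 275 segments with no difference in copy number, and a median of 7.16% of an animal's segments overlapped one of these.

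**Figure D4:**
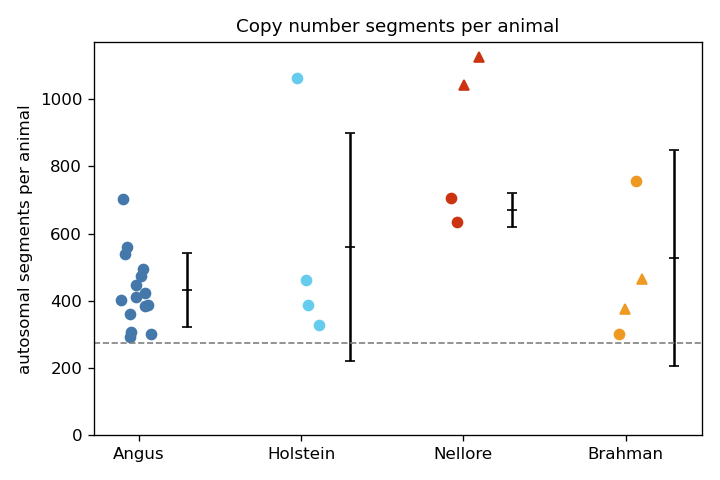
Number of autosomal segments per animal (vertical axis, from 0) by breed (horizontal axis), with circles for design 2, triangles for the further animals of design 1, and black bars for the mean ± SD of design 2. The dashed line marks the 275 segments of the self-hybridised reference, and Holstein-4 stands apart from the other Holstein at 1063.

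Some regions held segments in nearly all animals. Every gain or loss is relative to Angus-4, so one found in nearly all animals may lie in Angus-4 itself. Its own copy number cancels on the self-hybridised array. Gains on chromosome 15 from 46414861 to 46426107 were found in 27 of 27 animals, with a median of 1.72 in Angus and 0.08 on the self-hybridised array. Gains on chromosome 12 from 69766887 to 69807226 were found in 26 animals and on chromosome 10 from 26451007 to 26451522 in 25, with Angus medians of 0.43 and 1.24. Losses on chromosome 17 from 65456453 to 65456700 and on chromosome 11 from 87156618 to 87156981 were found in all 27 animals, with Angus medians of -1.47 and -0.98 against 0.07 and -0.33 on the self-hybridised array. The gain on chromosome 5 from 63249773 to 63250232, in 26 animals, and the losses on chromosome 11 from 107281637 to 107295650, chromosome 16 from 74343535 to 74343879 and chromosome 3 from 126266650 to 126285488, in all 27, also had a segment on the self-hybridised array. Angus medians in these 3 losses were -0.17, -0.10 and -0.03, and those of Brahman -0.23, -0.13 and 0.02. The window on chromosome 1 from 108878989 to 108922728, with gains in 26 animals, had an Angus median of 0.20 and 0.28 on the self-hybridised array.

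Repeat arrays with other probes correlated weakly with the first arrays. They were noisier, with a probe SD of 0.31 to 0.51 against 0.18 to 0.34 over the 23 animals of design 2. Red signals were well above background for 59.7% of probes for Holstein-2 and 63.5% for Brahman-1, against 88.4 to 96.2% on the other repeat arrays. Across 9621 windows with at least 3 probes of design 3, which are not independent, r between both arrays of an animal was 0.171 to 0.416 (median 0.194, 6 animals), against a median of 0.102 between different animals. For each of the 6 repeat arrays at least 1 other animal correlated more highly than the animal itself, among them 4 of 26 for Nellore-3 and 6 of 26 for Angus-3. Of the 14 regions named for the subspecies that hold probes of design 3, the mean of Nellore-2 and Nellore-3 minus that of Angus-2 and Angus-3 had the direction of the call in 7 of 8 higher and 6 of 6 lower regions. It kept at least 0.5 of its size on the first arrays in 3 of the higher and 4 of the lower regions. The first array of Nellore-3, nearer 0 than that of Nellore-2 at 63674162 on chromosome 5 and at 44084364 on chromosome 15, is part of that mean and lowers its size there. With Nellore-2 alone the numbers were also 3 and 4. Among them were chromosome 14 at 13267137, with -0.13 on the first and -0.09 on the repeat array, and chromosome 5 at 62272299, with -0.01 and -0.45. First-array differences that near 0 leave little to be kept. In the mean of both Nellore, the higher region without the direction of the call was that of chromosome 5 from 62969336 to 63803446, at -0.03. It also holds lower windows, and over its part to 63504627 the difference was 0.04 on the repeat arrays. Over the lower region of chromosome 5 from 63674162 to 63978607 the repeat arrays gave medians of -2.50 in Nellore-2, -2.50 in Nellore-3, -0.78 in Brahman-1, 0.04 in Angus-2 and -0.22 in Angus-3. On chromosome 2 from 93461024 to 93465953 Nellore-2 and Nellore-3 stood at 0.95 and 0.81 on the repeat arrays and at 1.12 and 1.12 on the first arrays. On chromosome 24 from 13062663 to 13121326 Nellore-2 stood at 0.20 on the repeat array against 1.69 on the first, and on chromosome 4 from 34811257 to 35516641 at 0.06 against 1.66. These regions held 29 and 509 repeat-array probes, against 30 and 30 first-array probes. Single windows of 10 first-array probes span 13062663 to 13119813 and 34811257 to 35506154. The repeat medians thus mostly cover DNA where the first arrays hold few probes. They do not show whether the named windows themselves repeat. On chromosome 13 from 19279216 to 19317947 Nellore-2 and Nellore-3 stood at -0.08 and -0.08 against -1.14 and -1.40 on the first arrays, and Holstein-2 at -0.07 against -1.26. On chromosome 15 from 46386257 to 46857914, lower in Holstein, Holstein-2 stood at 0.10 on the first array against 0.24 in Angus-2 and 0.19 in Angus-3, but at 1.21 on the repeat array against 0.72 and 0.64. On chromosome 11 from 98623308 to 98643341 Nellore-2 and Nellore-3 stood at 0.14 and 0.15 against -0.53 and -0.46.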

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

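Of the tests reported here, the limits for the repeat arrays over all lower windows and for isolated probes were set before their results were seen, and those for windows lower by at least 1, for shared profiles with and without chromosome 11, for Nellore-3 and for other splits of the animals were chosen after. How the test over all lower windows is read was also changed after its value was seen.

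Of 94 groups of 4 animals examined for a value far from the others, 12 held one, where chance gives about 1 in 20. These were Holstein-3 at 0.0432 on chromosome 15 at 46915258, Holstein-1 at 0.53 on chromosome 2 at 93461024 and Holstein-4 at 0.82 on chromosome 10 at 106191687. Among Nellore they were Nellore-1 at -1.10 on chromosome 7 at 49061514, Nellore-1 at -4.67 on chromosome 11 at 98623308 and Nellore-3 at -1.03 on chromosome 5 at 63803421. Brahman-1 stood apart from the other Brahman 5 times, at 2.74 on chromosome 5 at 63420204, 0.0721 on chromosome 24 at 13120167, -0.88 on chromosome 8 at 65224705, 0.17 on chromosome 29 at 7826985 and -0.27 on chromosome 13 at 54022591. Brahman-4 stood apart at 0.93 on chromosome 9 at 24834943. The self-hybridised reference, which was in no fit of the main comparisons, held 275 segments.

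Nellore and Brahman differed from each other in 10 of the 20 windows named for the subspecies (limma, adjusted p between 1.14e-13 and 0.0203). Nellore was higher by 1.72 on chromosome 11 at 35145542, 1.98 on chromosome 6 at 95551339, 1.68 on chromosome 24 at 13120167, 1.63 on chromosome 4 at 34811257 and 0.71 on chromosome 2 at 35240671. Nellore was lower by a difference of -3.01 on chromosome 5 at 63824732, -3.49 on chromosome 15 at 44148744, -1.68 on chromosome 8 at 65224705, -0.58 on chromosome 29 at 7826985 and -0.51 on chromosome 7 at 49061514.

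Nellore-3 stood nearer 0 than the other Nellore in windows of chromosomes 5 and 15 on its first array. Over the 4 windows below -2 in Nellore-1, Nellore-2 and Nellore-4 that hold repeat-array probes, its median was -0.97 on the first array and -2.90 on the repeat array, a ratio of 2.98. A wider range of ratios on the repeat design is argued against by Brahman-1, at -0.83 and -0.98 over the same windows, a ratio of 1.17. The ratio of Nellore-2 was 0.941, but it stood at -3.17 on its first array. At 63803421, 1 of these windows, red signals were well above background for 40% of values in Nellore, so its ratio had little room to grow. DNA of another animal, or a mixture, on 1 of the arrays of Nellore-3 may account for its change. The 4 windows lie in 2 regions, however, 3 of them on chromosome 5. No biological explanation was tested, and Nellore-3 was in no fit of the main comparisons.

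Windows lower in Nellore than in Angus could come from sequence variants under the probes, since a mismatch with the probe lowers signal without a change in copy number. On the repeat arrays, which use other probes, the median difference over 66 called lower windows was -0.02 (-0.0195), against -0.40 for the same animals on the first arrays, which met the limit set beforehand for variants. The 64 higher windows shrank as well, from 0.37 to 0.07, which mismatches in Nellore would not produce, so this value does not single out variants. Isolated probes were counted in indicine minus taurine, which also holds Brahman and Holstein, and not in Nellore against Angus. They gave 505 lower and 389 higher calls, a ratio of 1.298. A ratio under 1.5 had been set beforehand as counting against variants under isolated probes. Isolated probes nevertheless leaned more to lower calls than probes shifted on both sides (138 lower, 224 higher). The 12 of 33 windows lower by at least 1 that could be checked had a median of -1.15 on the repeat arrays (interquartile range -1.98 to -0.13) against -1.36 on the first, with 10 in the same direction, which argues against variants as the whole cause in these 12 but leaves single windows and those not checked open, and smaller losses cannot be told apart from variants because the repeat arrays lost both directions.

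Of 590 pairs of windows on different chromosomes called at least 1 higher in Nellore than in Angus, 12.9% correlated above 0.8 across animals after breed means were removed, against 1.19% of 420 pairs of lower windows and 0 of 19051 pairs of random windows. These pairs came from 20 windows in 4 regions and are not independent: 9 of 9 pairs of chromosomes 4 and 24 passed 0.8, 30 of 36 of chromosomes 4 and 6, 30 of 36 of chromosomes 6 and 24, 6 of 24 of chromosomes 6 and 11, 1 of 6 of chromosomes 4 and 11 and 0 of 6 of chromosomes 11 and 24. A candidate explanation for chromosomes 4, 24 and most windows of chromosome 6 is 1 repeated or duplicated sequence measured at several positions. That chromosome 11 shares this sequence is argued against by Holstein, whose median there differed by -0.84 from that on chromosomes 4 and 24. Part of chromosome 6 had a profile like that of chromosome 11, with r up to 0.993. Its windows at 95550820, 95551339 and 95551749 had Holstein means of -0.61, -0.77 and -0.43, against -0.80 and -0.72 on chromosome 11. A difference in copy number of such a sequence between breeds stays open and was not tested.

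Chance was tested by moving breed names among animals. Of 100 splits, the real split included, 1 called as many windows for the subspecies, with 563 in the real split and 8 in the highest other. That is the smallest share 100 splits can give, so chance alone is unlikely but not excluded. Moving breed names also adds real differences between breeds to the spread, which can lower counts in the other splits. Scan day is not excluded either, since the Brahman were scanned on a day without taurine animals. For Holstein and Angus 1 of 100 splits called as many, with 108 in the real split and 6 in the highest other. That makes chance alone unlikely but does not exclude scan day, since all Holstein were scanned on a day of their own. With scan day as a random block limma called 0 windows (3957 at an unadjusted p under 0.05). The named differences stayed between 0.962 and 1.01 times their size. That block cannot remove a scan-day effect from Holstein, so these values neither point to scan day nor exclude it. Sizes did fall without the 12 Angus of scan days 7 and 8, which also differed in X chromosome ratio. They were 0.0035, 0.0757, 0.511 and 0.629 times as large on chromosomes 8, 14, 11 and 6, and the other named differences moved less.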

How the results depend on the processing

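The fits with scan day and those without the 12 Angus of scan days 7 and 8, without noisy arrays, without Brahman and with dim signals raised were chosen after the data were seen, and the others were planned. Counts of windows are given for indicine against taurine (563), Holstein against Angus (108), Nellore against Angus (480), Brahman against Angus (443) and Nellore against Brahman (201), and the cause of a change was not tested unless stated.

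Normexp gave 2185, 7822, 980, 6558 and 540. It moved the share of higher calls from 56.0 to 37.3% for Nellore against Angus (366 higher and 614 lower, from 269 and 211) and from 49.9 to 64.1% for Brahman against Angus (4203 higher and 2355 lower, from 221 and 222). Means over probes gave 855 for the subspecies and 320 for Holstein. The filter on dim probes gave 192 for Holstein and 266 for Brahman against Angus. Dim signals raised to the lowest well above background gave 2783 (1194 higher and 1589 lower, a share of higher calls of 42.9% from 60.2%), 307, 543, 9235 and 539, with array centres moved as well. Windows of 5 probes gave 31 for Holstein, 868 for Nellore against Angus and 306 for Nellore against Brahman, and windows of 20 probes gave 169, 240 and 96, where fewer windows are tested. Round of slide use as a covariate gave 578 for Holstein, 195 for Brahman against Angus and 123 for Nellore against Brahman, and round B alone gave 92 for the subspecies and 97 for Brahman against Angus, with fewer animals. With the further 4 indicine animals the counts were 784 for Nellore and 1292 for Brahman against Angus and 675 for Nellore against Brahman. A difference of at least 0.3 left 270 for the subspecies, 24 for Holstein and 237 for Brahman against Angus. An adjusted p under 0.01 left 281 for the subspecies, 79 for Brahman against Angus and 120 for Nellore against Brahman, and limma left 0 for Holstein, with 5926 windows at an unadjusted p under 0.05.

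With scan day as a random block limma called 0 windows for Holstein (3957 at an unadjusted p under 0.05) and 142 for Brahman against Angus. Within scan day 2 the subspecies count was 331. Without the 12 Angus of scan days 7 and 8 the counts were 2 for Holstein, 301 for Nellore and 149 for Brahman, each against Angus, and without noisy arrays 34 for Holstein. Loess, the deposited value table, kept outlier probes, slide and slide position moved no count of windows by over 1.5 times.

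Leaving out animals in turn gave 293 to 590 for the subspecies (293 without Nellore-2, 342 without Brahman-3), 297 to 487 for Nellore against Angus (297 without Nellore-1, 298 without Nellore-2), 86 to 417 for Brahman against Angus (86 without Brahman-3) and 112 to 203 for Nellore against Brahman (112 without Nellore-1). For Holstein the range was 2 to 213, with 19 without Holstein-1, 10 without Holstein-2, 213 without Holstein-3, 2 without Holstein-4 and 70 without Nellore-1 or Nellore-2.

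Animal numbers in the labels do not pair the samples. Deviations of same-numbered animals correlated between -0.0922 and 0.132 (10 pairs), and 3 of 11 animals correlated best with an animal of their own number. With the animal number as a block the counts were 586, 2, 271, 5 and 140, and the differences in segments were 73.6 for the subspecies and 93.0 for Holstein.

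The segment difference between the subspecies kept its direction and passed 0.05 with a score of at least 10 (50.9), a mean of at least 0.5 (146), normexp (186), round A (248) and without Holstein-4 (173) or Brahman-4 (239). It was 87.7 to 239 with an animal left out. That between Holstein and Angus passed 0.05 with a score of at least 10 (41.0) and a running median (151), turned to -26.8 with a mean of at least 0.5, and was -39.7 to 205 with an animal left out, with -39.7 without Holstein-4. The median r between repeat and first arrays was 0.30 over windows with a log2 ratio of at least 0.3 in some animal, and 0.193 to 0.195 with an animal left out.

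Of the named windows, that on chromosome 8 at 86052068 turned to 0.55 for Holstein minus Angus with the replicate block, and that on chromosome 3 at 108959071 to 0.47 for Brahman minus Angus with normexp. Of 20 windows named for the subspecies, 6 stayed past the threshold in all their fits. Of 10 named for each other comparison, 0 did for Holstein, 7 for Nellore against Angus, 1 for Brahman against Angus and 4 for Nellore against Brahman. Green signals were well above background for 75.7% of probes on a Brahman array, which limits dim probes there. Gene results, gene lists and GC correction were not run, because probes could not be tied to genes or sequences.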

Other observations

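The regions in the next paragraph were chosen after their values were seen, by the number of neighbouring called windows (at least 6 for the subspecies and 5 for Brahman against Angus).

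Indicine cattle were higher than taurine cattle over 11 neighbouring called windows on chromosome 23 from 28622413 to 29749720, with a largest difference of 0.54 and means of 0.52 in Nellore and 0.17 in Brahman. On chromosome 7 from 21636878 to 21639092 there were 7 higher windows, up to 0.47, and on chromosome 13 from 204294 to 301693 another 7, up to 0.49. Chromosome 29 from 29276353 to 29417076 and chromosome 15 from 11481 to 46603 held 6 each, up to 0.43 and 0.43, as did chromosome 1 from 37734 to 62761 (up to 0.52) and from 59253319 to 59255210 (up to 0.47) and chromosome 20 from 2966553 to 2991318 (up to 0.27). The differences on chromosomes 7 and 29 were those of Nellore, with means over these windows of 0.65 and 0.34, against 0.03 and -0.28 in Brahman, -0.06 and -0.24 in Angus and 0.04 and -0.33 in Holstein. On chromosome 5 from 62228350 to 62478826, 6 called windows were lower, down to -0.78, beside the larger changes near 63 Mb. Brahman was higher than Angus over 5 windows on chromosome 15 from 49173153 to 49522217, up to 0.58, and over 5 on chromosome 19 from 45845011 to 45848074, up to 0.56.

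Over the 11 autosomal windows below -2 in Nellore-1, Nellore-2 and Nellore-4, on 2 chromosomes, Nellore-3 lay between -1.04 and -0.77 on its first array. On chromosome 8 at 65224705 it was the lowest Nellore, at -3.24 against -2.78 in Nellore-1. Nellore-3 and Nellore-4, the animals of scan day 1, held 1043 and 1124 segments, against 466 and 377 in Brahman-1 and Brahman-2 on the same array design and 1063 in Holstein-4.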
